A study of Rattus norvegicus with 22 samples.

How the data were processed

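RNA-seq was available for 22 rat adipose libraries in 4 groups: visceral fat from the mesentery and subcutaneous fat from the groin, each taken from rats with type 2 diabetes (T2DM) and from rats after duodenal-jejunal bypass (DJB), an operation that routes food past the duodenum. Per the labels' protocols, all rats had a high-fat diet and the treatment protocol names streptozotocin, a toxin of insulin-producing cells, at 30 mg/kg. RNA was extracted with Trizol, 10 ug of total RNA was used per library, and libraries followed standard Illumina protocols. Groups and replicate numbers were taken from the sample labels. The labels name no healthy, sham-operated or pre-operation group. All samples carry the same treatment text, which names streptozotocin and the bypass, so whether the T2DM rats had a sham operation or matched feeding is not known, and a DJB minus T2DM value can include effects of surgery or feeding. The labels do not say whether the replicates of a group came from separate rats, so p-values measure the spread between these samples, which includes technical spread.

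The deposited table holds raw read counts per gene and FPKM (fragments scaled by transcript length and library size) side by side for each library, per the file headers. The authors' FPKM and counts came from the same counting, because the ratio of FPKM to count was the same for each gene in every library up to 1 factor per library (SD of the log2 ratio 0.000747 over 11347 genes with at least 50 counts in all libraries). Reads were trimmed with cutadapt 1.9 and checked with FastQC, and the genome build was mRatBN7.2, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. The gene coordinates reach 282.724 Mb on chromosome 1, which is longer than that chromosome in the named build, so the build behind the coordinates is in doubt and no coordinates are reported. Values of gene families with near-identical members (immunoglobulins, keratins, major histocompatibility genes and casein genes) and of overlapping or antisense genes are uncertain, since reads shared between them could be counted under either gene.

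The test fixed before the data were examined was limma on log2(FPKM + 1), with edgeR's quasi-likelihood test named in its place if the table proved to hold raw counts. Raw counts were found, so edgeR 4.0.16 was the main test and limma 3.58.1 an alternative. Of 24286 genes, 14019 with an FPKM of at least 1 in at least 5 libraries were tested. Libraries were scaled by TMM (trimmed mean of M values; factors 0.543 to 1.39). A single model with 1 mean per group was fitted to all 22 libraries (common biological coefficient of variation 0.551, prior degrees of freedom 3.21). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 14019 genes, and the threshold was an adjusted p of 0.05. Standard errors (SE) were derived from the log2 fold change and its F statistic. Levels are given as CPM, counts scaled to the same library total with TMM factors, as mean ± SD over libraries. Total counts lay between 46824300 and 88829000 per library, and counting error is then small beside the spread between libraries for all but the lowest genes. For a gene with 0 counts in a group only levels are given.

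The 5 contrasts tested were DJB minus T2DM in visceral fat, the same in subcutaneous fat, the difference between these 2 effects (interaction), and visceral minus subcutaneous fat within the T2DM and within the DJB group. Before the data were examined, 39 gene lists were fixed, covering adipokines, hormone signalling, lipid and mitochondrial metabolism, inflammation and stress, depot development and markers of the cell types that fat samples can hold. Lists were tested with camera in limma, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 38 lists with at least 5 tested members. The exocrine pancreas list had 4 tested members and was not tested. An exact permutation test of the mean log2 CPM of each list per library was added after the data were seen. Members of 3 lists named by the study's title (adipokines, growth hormone signalling, adiponectin receptors and assembly; 62 tested genes) were also adjusted over the list alone.

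Genes are named in the text by a rule fixed before the data were examined. In each comparison these are the 8 called genes with the largest and the 8 with the smallest log2 fold change, among genes with a symbol that is not a bare locus identifier and a mean FPKM of at least 2 in a group. To these were added 15 genes of the growth hormone, adiponectin and insulin axis and up to 4 members with the smallest p of each list described. Genes outside the rule are named as chosen after their values were seen.

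The test steps were tested on simulated data with the real library sizes, in which 200 genes were changed. Counts were drawn for each gene independently, around its mean over the 4 groups and with its estimated dispersion. Such data hold no libraries that stand apart over many genes at once, so the false calls below do not give the error rate in the real data. In the visceral comparison 14 of 100 genes changed 2-fold and 66 of 100 genes changed 4-fold were recovered, with 2 false calls among 13819 unchanged genes. In the subcutaneous comparison these were 6, 61 and 4, for the interaction 2, 32 and 3, between depots in T2DM 9, 62 and 0, and between depots after DJB 14, 62 and 4.

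Alternatives fixed in advance were limma on log2(FPKM + 1) and on log2(FPKM + 0.1), DESeq2 1.42.0, median-ratio and TPM scaling, no filter and a filter of FPKM 5, a fit of the compared groups only, fits without a dispersion trend and with robust estimation, a 2-fold minimum, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after the data were seen left out visceral T2DM libraries 2, 3 and 4 or 2 and 5, left out the mitochondrial genes, used the mitochondrial share or the milk gene level as a covariate, or removed each library's trend of expression on transcript length. Computations used R 4.3.3 with data.table version 1.17.8, and Python 3.11.15 with matplotlib 3.10.9 for the plots.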

Results

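The data are RNA-seq gene counts from 22 libraries of rat fat, each with 4 months in its sample title. Visceral fat of the mesentery was sampled in 6 T2DM and 6 DJB libraries, and subcutaneous fat of the groin in 5 T2DM and 5 DJB libraries. Libraries are named by depot, group and replicate number. Total counts were 58951500 to 79629700 in the visceral T2DM libraries, 58976700 to 88829000 in the visceral DJB libraries, 49155600 to 83319300 in the subcutaneous T2DM libraries and 46824300 to 76835900 in the subcutaneous DJB libraries.

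The libraries differed in composition as well as in depth. Mitochondrially encoded genes took 27.4% ± 11.2 (SD, n = 6) of the counts in visceral T2DM, 29.5% ± 11.7 (n = 6) in visceral DJB, 9.58% ± 4.19 (n = 5) in subcutaneous T2DM and 22.7% ± 8.42 (n = 5) in subcutaneous DJB. By exact two-sided permutation tests the share differed between the treatment groups in subcutaneous fat (p = 0.0159) and between the depots in T2DM (p = 0.00866), and a difference was not shown in visceral fat (p = 0.749) or between the depots after DJB (p = 0.312). Genes of milk proteins and of the milk-secreting cells of the mammary gland took 0.0595% to 18.8% of the counts in subcutaneous T2DM libraries and 0.0800% to 7.93% in subcutaneous DJB libraries, against at most 0.0571% in any visceral library. The groin fat pad of the rat holds mammary gland tissue. The most abundant of these genes, the casein gene Csn1s1, reached 172134 CPM in subcutaneous T2DM library 4.

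In visceral fat, nuclear genes of mitochondrial energy metabolism were lower after DJB than in T2DM. Of 73 tested genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 66 fell and 0 rose, with a median log2 fold change of -1.97. Cox5b and Cox8a, subunits of cytochrome c oxidase, changed by -2.93 (SE 0.67) and -2.62 (SE 0.60) on the log2 scale, and Ndufb5 and Ndufv3 of complex I by -2.34 and -1.82. The mean log2 CPM of the 73 genes was 8.55 and 7.57 in visceral T2DM libraries 2 and 5, 4.79 to 5.69 in the other 4 and 4.75 to 5.27 in the 6 DJB libraries, and without libraries 2 and 5 the median was -0.36 with 70 of 73 genes negative. Of 24 genes of fatty acid oxidation 18 fell (median -1.97), among them Eci1 by 10.4-fold, the long-chain acyl-CoA dehydrogenase Acadl by 6.36-fold and Ppara, the nuclear receptor that drives fatty acid oxidation genes, by 7.01-fold. Of 20 tricarboxylic acid cycle genes 13 fell (median -1.38; Sdhb -1.89, Idh3b -1.70, Suclg1 -1.64), and of 21 genes of branched-chain amino acid breakdown 9 fell (median -1.22; Mccc1 -1.42, Ivd -1.22). The 4 lists each had adjusted p = 0.424 with an estimated correlation. Without T2DM libraries 2 and 5 the other medians were -0.80 for fatty acid oxidation (24 of 24 negative), -0.53 for the tricarboxylic acid cycle and -0.63 for branched-chain breakdown, and no member of the 4 lists was called. In these 2 libraries the deviation of a gene from its mean over all libraries was negatively correlated with transcript length (Spearman rho -0.51 and -0.38), against -0.10 to 0.28 in the other 10 visceral libraries. With the length trend removed 21 of 73 oxidative phosphorylation genes were called (median -1.22), 9 of 24 for fatty acid oxidation (-1.74), 4 of 20 for the tricarboxylic acid cycle (-1.16) and 5 of 21 for branched-chain breakdown (-1.09). With TPM scaling the oxidative phosphorylation median was -1.24. Ppara without T2DM library 5 had -2.09 (adjusted p = 0.0616 by edgeR).

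Other adipocyte groups in visceral fat had the same sign. Of 17 thermogenic adipocyte genes 4 fell (median -1.61): Cidea, a lipid droplet protein gene of brown fat, by 12.7-fold, Cpt1b, the muscle and brown fat carnitine palmitoyltransferase, by 3.46 on the log2 scale, Fabp3 by 9.95-fold and Acot2 by 3.05-fold (adjusted p = 0.490 with an estimated correlation). Visceral T2DM library 5 stood apart for these genes, with a thermogenic mean log2 CPM of 6.15 against 3.06 to 4.27 in the other T2DM libraries, Cidea at 1001 CPM against 24.4 to 201 and Cpt1b at 1047 against 17.0 to 107. Without it the folds were 4.42 for Cidea (adjusted p = 0.0542 by edgeR), 3.02 for Cpt1b (0.0930), 5.75 for Fabp3 (0.102) and 1.92 for Acot2 (0.143). Among 22 adipocyte differentiation genes 3 fell (median -0.87), including the transcription factor Klf5 by 27.2-fold and the adipogenic gene Adig by 11.3-fold (adjusted p = 0.585 with an estimated correlation). Klf5 had -1.05 without T2DM libraries 2, 3 and 4, and Adig -1.92 without library 2, and neither was then called. Adipocyte markers (median -1.39, 0 of 17 genes called), fatty acid and triglyceride synthesis (median -1.01, 0 of 26) and lipolysis and lipid droplet genes (median -1.08, 1 of 25 lower, again Cidea) were lower as lists, with adjusted p = 0.719, 0.585 and 0.719 with an estimated correlation. Without T2DM libraries 2 and 5 the medians were -0.70 for adipocyte markers and -0.47 for adipocyte differentiation, and with TPM scaling -0.57 for differentiation and -0.70 for lipolysis. Members nearest the threshold were Cfd (-2.23, adjusted p = 0.0800 by edgeR), Tmem120a (-1.79, 0.0830), the triglyceride synthesis genes Dgat1 (-1.83, 0.0509) and Agpat2 (-2.37, 0.0542), and the adrenergic receptor gene Adra2a (1.58, 0.0552).

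Lists that were higher in visceral fat after DJB were endothelial markers (median 1.03, 14 of 14 genes positive, 1 called), endoplasmic reticulum stress genes (median 0.58, 3 of 21 called) and extracellular matrix genes (median 0.58, 0 of 32 called, and 0.33 without T2DM libraries 2 and 5). These had adjusted p = 0.424, 0.585 and 0.719 with an estimated correlation. Flt4, a receptor of lymphatic endothelium, rose by 2.91-fold (SE 0.42 on the log2 scale), and Tie1 had a log2 fold change of 1.05 (adjusted p = 0.0948 by edgeR). The called chaperone genes Hspa5, Hsp90b1 and Pdia4 rose by 3.16-fold, 2.70-fold and 2.49-fold, and Hyou1 had 1.51 (adjusted p = 0.0554 by edgeR). Their levels were high in 2 libraries: Hspa5 was at 2043 and 2186 CPM in visceral DJB libraries 5 and 6 and at no more than 480.7 CPM in the other 4. Among matrix genes Lox had 1.92 (adjusted p = 0.114) and Tgfb1 0.63 (adjusted p = 0.122) by edgeR. Mammary and skin epithelium markers were lower (median -3.04, 7 of 15 called), with Krt15, Tp63, Krt5 and Dsp at -7.36, -6.75, -6.60 and -3.87 (adjusted p = 0.424 with an estimated correlation). Without visceral T2DM libraries 2, 3 and 4, in which the epithelial keratin gene Krt7 was at 555.5, 624 and 434 CPM, the list median was -1.16 and that of endothelial markers 0.66. Keratin reads are uncertain as those of a gene family.

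Camera with the preset correlation put these 13 lists past the threshold, 3 higher and 10 lower, with adjusted p from 3.67e-30 for oxidative phosphorylation and 1.86e-15 for fatty acid oxidation to 0.00963 for lipolysis. None of the 13 passed with an estimated correlation. In the exact permutation test of the list mean per library, 4 of 38 lists passed (adjusted p = 0.0411) and 11 had an unadjusted p under 0.05. The mean log2 CPM of thermogenic genes differed by -1.53 (SD 0.40 in DJB, 1.18 in T2DM), of fatty acid oxidation by -1.39 (SD 0.33 and 1.03), of adipocyte differentiation by -0.74 (SD 0.25 and 0.22) and of endothelial markers by 1.16 (SD 0.20 and 0.87). Oxidative phosphorylation did not pass (exact adjusted p = 0.0897).

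**Figure D1:**
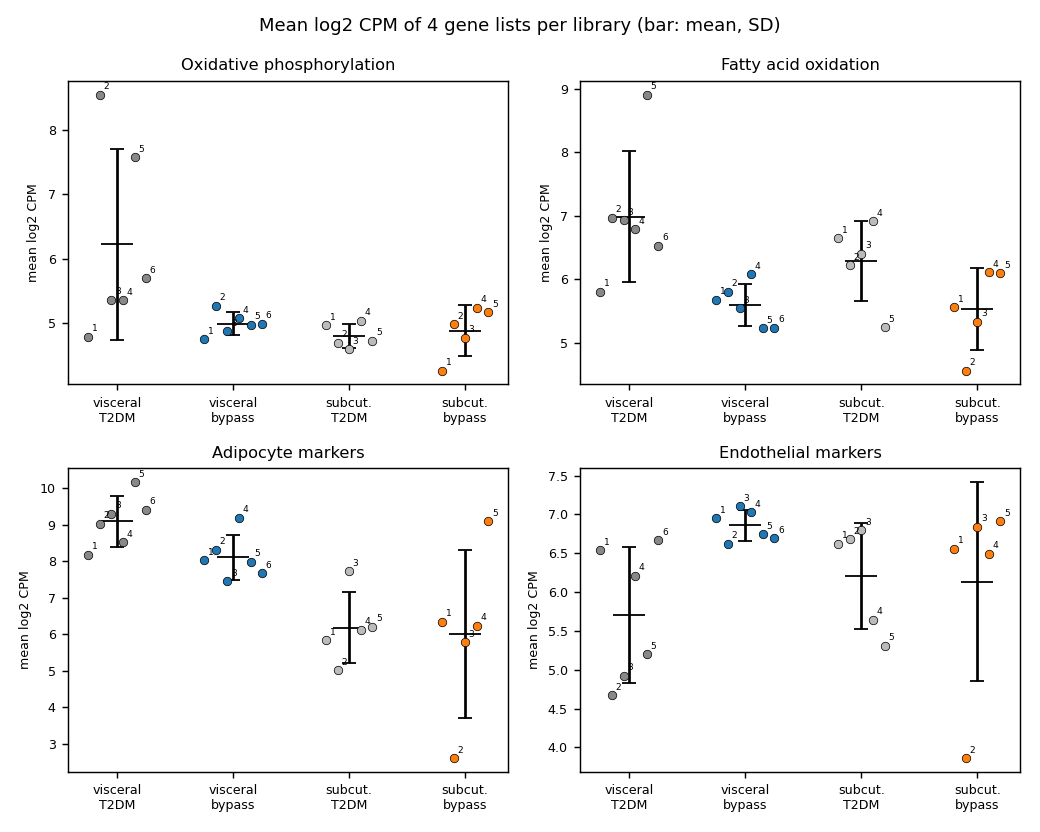
Mean log2 CPM of 4 gene lists in each of the 22 libraries, with points numbered by replicate and bars giving the group mean and SD. Visceral T2DM libraries 2 and 5 stand highest for oxidative phosphorylation (8.55 and 7.57), while endothelial markers were lowest among visceral libraries in T2DM libraries 2, 3 and 5 (4.67, 4.92 and 5.20).

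The other 25 lists did not pass in visceral fat. Their median log2 fold changes were 0.15 for growth hormone signalling, -0.01 for adiponectin receptors and assembly, -0.52 for adipokines, 0.06 for insulin signalling, -0.32 for cholesterol synthesis, 0.07 for gut hormone and bile acid receptors, 0.45 for inflammatory cytokines and -0.12 for interferon response. Values were 0.20 for glucocorticoid response, 0.13 for circadian clock, 0.26 for immediate early genes, -0.23 for cell cycle, 0.11 for subcutaneous and -0.02 for visceral developmental genes. Cell type markers had 0.20 for stromal progenitors, 0.03 for macrophages, 0.01 for T and NK cells, -0.27 for B and plasma cells (0.19 with TPM scaling), -1.05 for neutrophils and mast cells and -0.20 for smooth muscle and pericytes. The last markers had -1.76 for mesothelium, -0.52 for skeletal muscle, -1.51 for intestinal epithelium, 0.49 for Schwann cells and -0.44 for blood. With TPM scaling adipokines had -0.03, gut hormone receptors 0.21, glucocorticoid response 0.39, stromal progenitors 0.37, macrophages 0.41 and T and NK cells 0.41. Without 1 library some passed with the preset correlation. Immediate early genes did without T2DM libraries 1, 4 or 6 or DJB libraries 4 or 6 (camera adjusted p = 0.00654 to 0.0458, median 0.61 without T2DM library 1). Inflammatory cytokines did without T2DM library 1 (0.0125, median 0.68) or DJB libraries 1, 3 or 4 (at most 0.0496). Interferon response passed without T2DM library 2 (0.0318, median -0.06) or DJB libraries 1 or 2 (0.0331 and 0.0322, the second with a median of -0.21). Stromal progenitors passed without T2DM library 1 (0.0412, median 0.38) and macrophages without T2DM library 2 (0.0124, median 0.39). Mesothelium passed without T2DM library 5 (0.0136) and neutrophils and mast cells without DJB library 5 (0.0495). The mean had the opposite sign to the median for growth hormone and insulin signalling, gut hormone receptors, both sets of developmental genes and T and NK cells.

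Among single genes in visceral fat, the largest increases after DJB were in genes of plasma proteins made mainly by liver. Serpina1 (log2 fold change 6.09, SE 1.67, adjusted p = 0.0427 by edgeR), Azgp1 (5.36), the hemopexin gene Hpx (5.18), the haptoglobin gene Hp (5.04), Apoa1 (4.96) and Itih3 (3.68) rose, as did the adipokine gene Serpina12 (4.32) and the neutrophil growth factor gene Csf3 (3.90). The plasma protein genes were high in 1 or 2 libraries: Hp was at 824 CPM in visceral DJB library 2 and 59.9 in library 1, and between 1.84 and 10.9 in the other 4, against 4.56 ± 3.67 (SD, n = 6) in T2DM. Csf3 was at 36.8 and 17.2 CPM in DJB libraries 5 and 6.

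The largest decreases were in epithelial genes, several of them of the urothelium that lines the bladder. The uroplakin genes Upk3a (-8.06, SE 1.63, adjusted p = 0.0291 by edgeR) and Upk2 (-8.32), Gdpd3 (-8.35), Bnipl (-8.29), Fxyd3 (-7.88), Psca (-7.78), Krt20 (-7.75) and Sptssb (-7.60) fell. Upk3a was at 480.5, 326 and 149 CPM in visceral T2DM libraries 2, 3 and 4 and at no more than 8.46 CPM in the other 9 visceral libraries. Bnipl had 2503 counts over the 6 T2DM libraries and 7 over the 6 DJB libraries, and Krt20 1691 and 7, so their folds rest on few counts. For 13 tested urothelial genes, a list chosen after their values were seen, the median was -7.18, and -2.47 without libraries 2, 3 and 4.

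Over all genes, 658 of 14019 were called in visceral fat by edgeR at an adjusted p of 0.05, 59 higher and 599 lower after DJB, and 3106 had an unadjusted p under 0.05. The count rested on single libraries. It was 1744 without visceral T2DM library 1, 67 without T2DM library 2 and 159 without T2DM library 5, and 2, 1, 7, 1 and 1 without DJB libraries 1, 2, 3, 5 and 6. Fndc5 was called without each of DJB libraries 1, 2, 5 and 6, and the calls of the other genes named here ended without library 2, 5 or 6. Limma called 0 genes on log2(FPKM + 1) and 0 on log2(FPKM + 0.1), with 1765 and 1786 at an unadjusted p under 0.05, and DESeq2 called 1459 (215 higher, 1244 lower). The count was 115 with TPM scaling (1 higher, 114 lower), 237 with no filter, 1 when only the groups compared were fitted, 277 with the length trend removed, 0 without T2DM libraries 2, 3 and 4 (1436 at an unadjusted p under 0.05) and 73 without T2DM libraries 2 and 5.

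**Figure D2:**
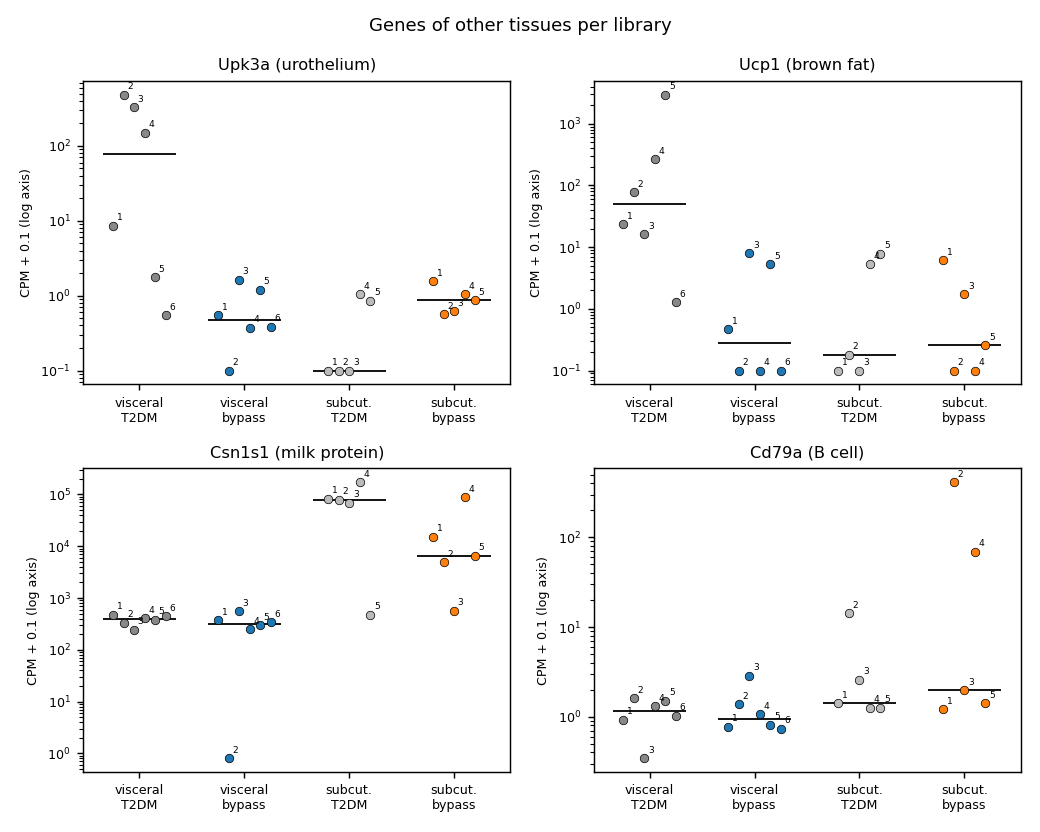
CPM + 0.1 on a log axis of Upk3a, Ucp1, Csn1s1 and Cd79a in each library, with points numbered by replicate and bars at the group median. Upk3a is high in visceral T2DM libraries 2, 3 and 4, Ucp1 in visceral T2DM library 5 (2944 CPM), Csn1s1 in most subcutaneous libraries and Cd79a in subcutaneous DJB library 2 (412 CPM).

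The series title names a growth hormone and adiponectin axis in visceral fat, and the members of 3 fixed lists were examined for it. Adipoq, the adiponectin gene, was at 3203 ± 2158 CPM (SD, n = 6) in visceral T2DM and 1412 ± 830 (n = 6) in visceral DJB, a log2 fold change of -1.18 (SE 0.70, adjusted p = 0.333 by edgeR). The growth hormone receptor gene Ghr was at 321 ± 108 and 248 ± 66.5 CPM (-0.37, SE 0.46, adjusted p = 0.681 by edgeR). Signal transducers of that receptor had -0.02 (Stat5a), 0.60 (Stat5b) and 0.65 (Jak2), its feedback inhibitors 0.88 (Socs2) and -0.12 (Cish), and its target Igf1 -0.26. The adiponectin receptor genes Adipor1 and Adipor2 had -0.21 and -0.11, the leptin gene Lep 0.94, the adipocyte regulator Pparg -0.66, the insulin-responsive glucose transporter gene Slc2a4 -1.48 and the insulin receptor gene Insr 0.02. The brown fat uncoupling protein gene Ucp1 had -7.95 (SE 2.38, adjusted p = 0.0556 by edgeR), with 2944 CPM in visceral T2DM library 5 and 1.20 to 265 CPM in the other T2DM libraries. None of these 15 genes passed the test.

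Of the 62 tested genes of the 3 lists, 6 were called in visceral fat by edgeR. Of these 3 rose, among them Serpina12 and the chaperone gene Hspa5, and Fndc5 (16.1-fold, SE 0.56 on the log2 scale, adjusted p = 0.00602), the binding protein gene Igfbp2 (59.3-fold) and Ppara fell. Igfbp2 was at 93.4, 122 and 68.8 CPM in visceral T2DM libraries 2, 3 and 4, which also held the uroplakin genes, at 4.93, 1.01 and 1.23 in libraries 1, 5 and 6 and at 0.456 to 1.24 in DJB, and without libraries 2, 3 and 4 it had -1.55 (adjusted p = 0.632 by edgeR). Fndc5 encodes the precursor of irisin, and its level in each of the 6 DJB libraries (0.453 to 1.13 CPM) lay below that of each T2DM library (2.19 to 21.8 CPM). It was at 8.86, 21.8, 13.0 and 20.3 CPM in T2DM libraries 2, 3, 4 and 5, and at 2.21 and 2.19 in libraries 1 and 6. Adjusted over the list alone, 11 genes passed, adding Cfd, Igfbp4, Nrg4, Socs1 and Stat3. The count of 6 became 14 without visceral T2DM library 1, 3, 2 and 3 without T2DM libraries 2, 5 and 6, and 1 without each of DJB libraries 1, 2, 3, 5 and 6. It was 2 with TPM scaling, 3 with no filter, 11 by DESeq2, 0 by limma with either pseudocount or when only the groups compared were fitted, 0 without T2DM libraries 2, 3 and 4 and 2 without T2DM libraries 2 and 5.

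**Figure D3:**
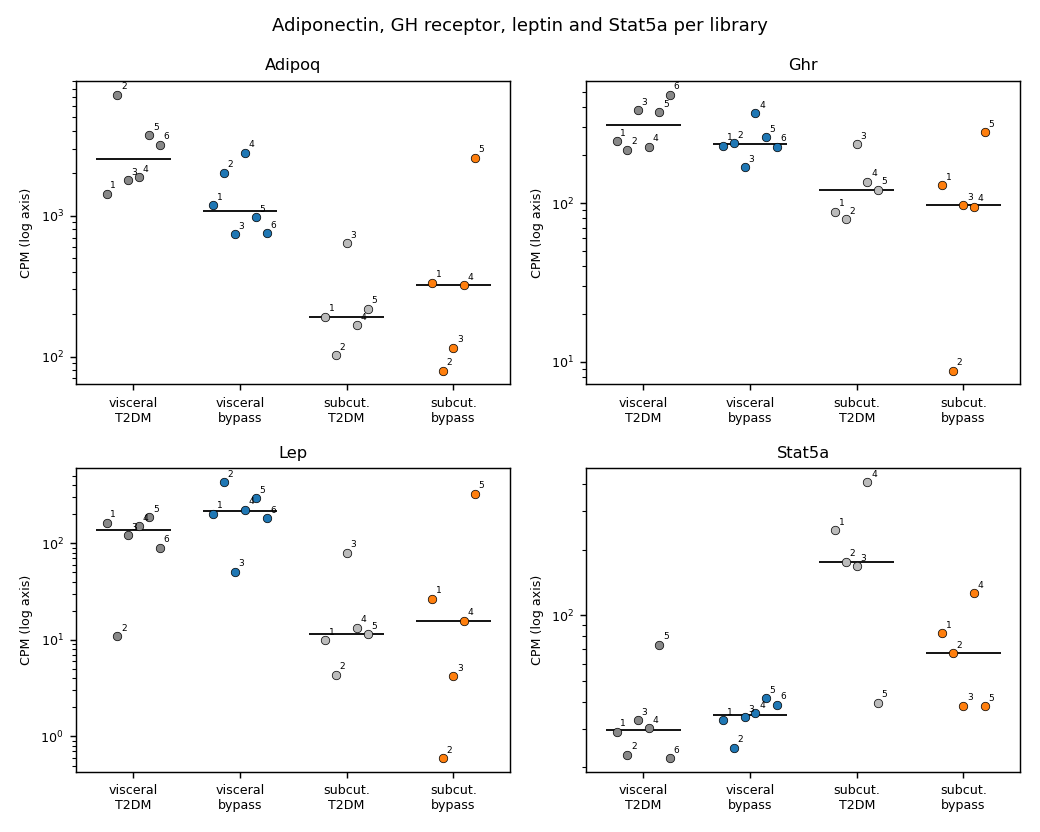
CPM on a log axis of Adipoq, Ghr, Lep and Stat5a in each library, with points numbered by replicate and bars at the group median. In visceral fat the T2DM and DJB libraries overlap for all 4 genes, and Stat5a is highest in subcutaneous T2DM (208 ± 135 CPM, SD, n = 5).

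In subcutaneous fat no gene was called, and the smallest adjusted p belonged to the tryptophan-degrading enzyme gene Ido1. Ido1 had a log2 fold change of -6.37 (SE 1.09, adjusted p = 0.115 by edgeR), and the interferon-inducible GTPase genes Irgm and Igtp, chosen after their values were seen, had -1.28 (SE 0.24) and -1.88 (SE 0.42), both with an adjusted p of 0.123 by edgeR. Irgm was at 77.4 ± 27.8 CPM (SD, n = 5) in T2DM and 31.8 ± 5.41 (n = 5) in DJB. In visceral fat the same 3 genes fell, Ido1 by 32.4-fold, Igtp by 3.47-fold and Irgm by 2.22-fold, and in both depots each was lower in every DJB library than in every T2DM library of that depot. The transcription factor gene Irf1 fell by 2.34-fold in visceral fat and had -0.84 in subcutaneous fat (adjusted p = 0.286 by edgeR).

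**Figure D4:**
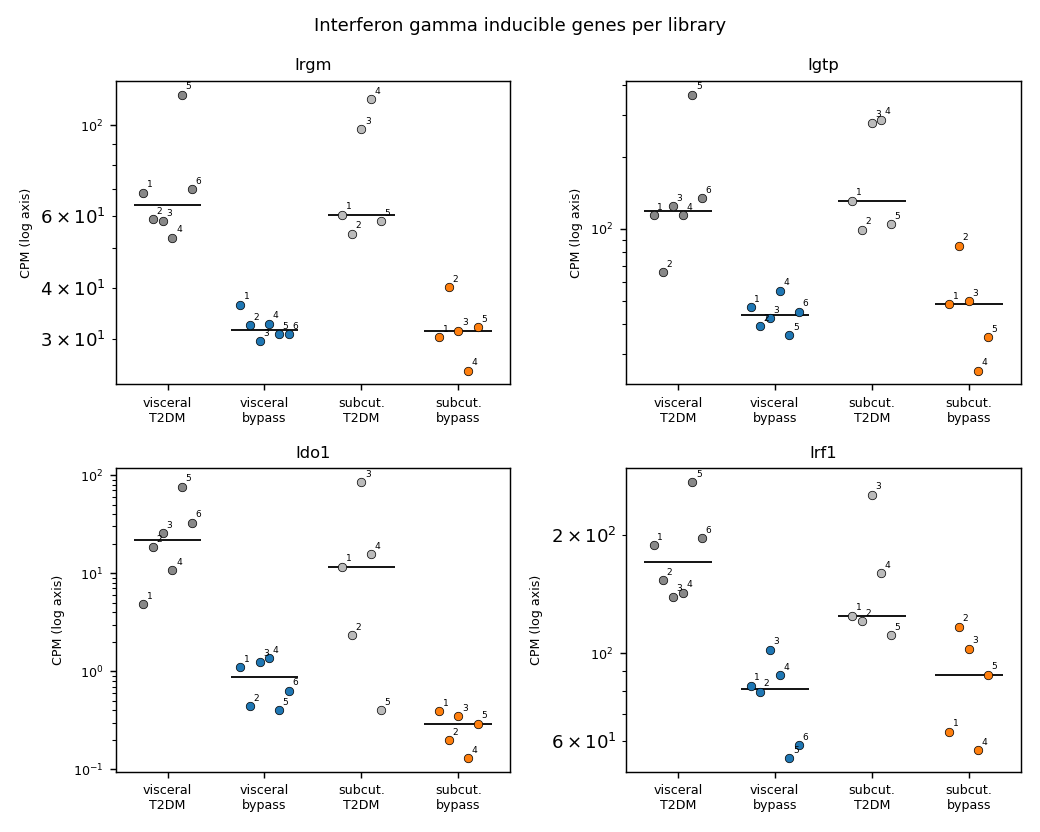
CPM on a log axis of Irgm, Igtp, Ido1 and Irf1 in each library, with points numbered by replicate and bars at the group median. For Irgm, Igtp and Ido1 every DJB library lies below every T2DM library of the same depot, while for Irf1 the subcutaneous groups overlap.

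By list, T and NK cell markers (median 2.95, 0 of 19 called) and B and plasma cell markers (2.79, 0 of 10) were higher in subcutaneous fat after DJB (adjusted p = 0.935 for both with an estimated correlation). The lymphocyte genes Ccr7, Tcf7, Cd79a and Fcrla had 4.62, 2.90, 4.58 and 4.65, each with an adjusted p of 0.244 by edgeR. These lists followed subcutaneous DJB library 2, where the mean log2 CPM was 6.52 for T and NK markers and 7.31 for B and plasma markers, and the adipocyte marker mean was 2.61. Without it the medians were 0.37 and 0.56, and neither list passed (camera adjusted p = 0.244 and 0.540).

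Lists that were lower in subcutaneous fat after DJB were fatty acid and triglyceride synthesis (median -0.89, 0 of 26 called; Fads1 -2.36, Fads2 -2.96, Acly -1.63), fatty acid oxidation (-0.48, 0 of 24; Acot1 -2.69), branched-chain amino acid breakdown (-0.35, 0 of 21; Mmut -0.79, Ivd -0.57), and mammary and skin epithelium markers (-1.36, 0 of 15; Csn3 and Elf5 -2.13). With an estimated correlation the first had adjusted p = 0.918 and the others 0.935. Fasn, the fatty acid synthase gene, was at 6309 to 26955 CPM in subcutaneous T2DM libraries 1 to 4, where Csn1s1 was at 68724 to 172134 CPM. In subcutaneous T2DM library 5 Fasn was at 110.9 and Csn1s1 at 473.5 CPM. Circadian clock genes (-0.34, 0 of 18; Hlf -1.85, Bhlhe41 -1.51) and interferon response genes (-0.13, 0 of 21; Gbp2 -1.45, Gbp5 -1.85) completed the 8 lists called by camera with adjusted p from 1.22e-08 to 0.0228. Clock and interferon response genes had adjusted p = 0.935 with an estimated correlation, and none of the 8 lists passed in the exact test of list means (0 of 38 lists with an unadjusted p under 0.05). The call for branched-chain breakdown ended without DJB library 1 (camera adjusted p = 0.0575), that for clock genes without T2DM library 4 (0.0544) or DJB library 2 (0.110), and that for interferon response without T2DM library 1 (0.116) or 3 (0.184) or DJB libraries 1, 3, 4 or 5 (0.208, 0.106, 0.322 and 0.167), with the median at 0.13 without T2DM library 3. Without DJB library 2, where the interferon response mean stood highest in its group, the interferon response median was -0.68 (camera adjusted p = 2.16e-13). With TPM scaling the medians were -0.72 for fatty acid oxidation, -0.69 for branched-chain breakdown, -0.64 for clock genes and -0.45 for interferon response.

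Other lists passed in subcutaneous fat only without 1 library, some with opposite signs. Adipocyte markers (median 0.63 over all libraries) had 0.96 without DJB library 2 (camera adjusted p = 0.000121) and -0.72 without DJB library 5 (0.00123). Lipolysis (0.38) had 0.52 (0.000121) and -0.26 (0.0278) without these libraries, and adipocyte differentiation (0.13) had 0.38 (0.0121) and -0.19 (0.0463). Cell cycle genes (0.59) had -0.48 without DJB library 2 (0.0186), and 0.82, 0.83 and 0.89 without DJB libraries 5 and 3 and T2DM library 2 (0.00413, 0.00606 and 0.0274). Without DJB library 2 endothelial markers (0.61), Schwann cells (0.69), immediate early genes (0.42) and subcutaneous developmental genes (0.47) also passed, with adjusted p from 9.24e-05 to 0.0287. Visceral developmental genes passed without DJB library 2 or T2DM libraries 2 or 3 (0.53, 0.46 and 0.67). Macrophage markers (-0.44) passed without T2DM libraries 1, 2 or 4 (-0.62, -0.54 and -0.65) or DJB libraries 1 or 3 (-0.70 and -0.65), with adjusted p from 0.000667 to 0.0292. Extracellular matrix (-0.14) passed without T2DM libraries 1 or 4 (-0.33 and -0.36) or DJB libraries 1 or 3 (-0.86 and -0.26), and stromal progenitors (-0.22) without T2DM library 4 (-0.31) or DJB library 1 (-0.56). Single libraries also gave a call for adipokines (-0.35, DJB 5), neutrophils and mast cells (-0.96, DJB 1, and -0.32, DJB 5), oxidative phosphorylation (0.25, DJB 1), smooth muscle (-0.44, DJB 3) and glucocorticoid response (-0.41, DJB 4). The number of lists called was 14 without DJB library 2 and 13 without DJB library 5.

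The axis genes in subcutaneous fat had log2 fold changes of 1.38 for Adipoq (SE 0.77, adjusted p = 0.646 by edgeR), -0.12 for Ghr, -1.56 for Stat5a (SE 0.45, adjusted p = 0.244 by edgeR), -0.21 for Stat5b, -0.09 for Jak2, 0.31 for Socs2, -1.38 for Cish, 0.33 for Igf1, -0.24 for Adipor1 and 0.07 for Adipor2. Pparg had 0.86, Slc2a4 0.29, Insr -1.09, Ucp1 -0.72 and Lep 1.65. Adipoq was at 263 ± 214 CPM (SD, n = 5) in T2DM and 685 ± 1063 (n = 5) in DJB, where library 5 reached 2576 CPM, and without that library the log2 fold changes were -0.31 for Adipoq and -1.01 for Lep. None of the 62 listed genes was called, and 1 (Serpina12) passed adjusted over the list alone. EdgeR called 0 genes in all, with 1259 at an unadjusted p under 0.05. Limma called 0 with either pseudocount (934 and 793 at an unadjusted p under 0.05), and DESeq2 called 168 (81 higher, 87 lower). Leaving out a library gave 29 calls without DJB library 2, 14 without DJB library 3, 9 without T2DM library 5 and 1 without T2DM library 2. TPM scaling moved the median of all genes from 0.05 to -0.21.

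The interaction asks whether DJB acted differently in the depots. In mitochondrial lists the DJB effect was lower in visceral than in subcutaneous fat, for oxidative phosphorylation (median difference -2.22, 73 of 73 genes negative; Cox5b -3.35, Cycs -2.30), the tricarboxylic acid cycle (-1.45), fatty acid oxidation (-1.28; Etfb -2.27), branched-chain amino acid breakdown (-0.79) and thermogenic genes (-1.50; Cpt1b -4.39, Cidea -3.75). Endothelial markers (0.66; Prox1 3.41), extracellular matrix (0.71), endoplasmic reticulum stress (0.74; Pdia4 1.41) and circadian clock genes (0.64) had positive differences. These 9 lists had adjusted p = 0.611 with an estimated correlation. Camera called 20 lists, 8 higher and 12 lower, and none passed with an estimated correlation (adjusted p = 0.611 to 0.650). The same 9 lists stayed past the camera threshold without each library in turn, with medians of 0.45 for extracellular matrix and 0.37 for endothelial markers without subcutaneous DJB library 2. With TPM scaling the medians were -1.07 for oxidative phosphorylation, -0.83 for the tricarboxylic acid cycle, -0.58 for fatty acid oxidation, -0.25 for branched-chain breakdown and -1.03 for thermogenic genes, and 1.30 for endoplasmic reticulum stress and 0.99 for clock genes. Visceral T2DM libraries 2 and 5, with the high oxidative phosphorylation means given above, enter this contrast too. Leaving out 1 library at a time keeps at least 1 of these 2, so it cannot show whether the mitochondrial differences rest on both. Without both, camera called 16 lists (6 higher, 10 lower), and the oxidative phosphorylation median of the visceral effect alone was -0.36. The endoplasmic reticulum stress mean log2 CPM was 7.49 and 7.51 in visceral DJB libraries 5 and 6. It was 6.12 to 6.44 in the other visceral DJB libraries and 6.15 to 6.55 in visceral T2DM. Leaving out 1 library keeps at least 1 of these 2 DJB libraries, so it cannot show whether that list rests on both. The clock means of subcutaneous T2DM libraries 1 to 4, given above, also enter the interaction.

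The other 11 lists called for the interaction lost the camera call without at least 1 library. Growth hormone signalling (median 0.31, camera adjusted p = 0.0497) lost it without visceral T2DM libraries 2 to 6, subcutaneous T2DM libraries 1, 2, 3 or 5, visceral DJB libraries 1 or 3 or subcutaneous DJB libraries 2, 3 or 5 (adjusted p = 0.0501 to 0.112, medians 0.14 to 0.39). Mesothelium markers (-3.34) lost it without visceral T2DM libraries 1 to 4, subcutaneous T2DM libraries 1, 4 or 5, visceral DJB libraries 1, 3, 5 or 6 or subcutaneous DJB libraries 1, 4 or 5 (0.0551 to 0.195). Adipocyte differentiation (-1.33) lost it without visceral T2DM libraries 3 or 6, subcutaneous T2DM library 4, visceral DJB libraries 5 or 6 or subcutaneous DJB libraries 1, 3 or 4 (0.0501 to 0.0777). Stromal progenitor markers (0.48) lost it without visceral T2DM libraries 3, 4 or 5, visceral DJB library 1 or subcutaneous DJB libraries 2 or 5 (adjusted p = 0.0534 to 0.407, the last with a median of 0.26 without subcutaneous DJB library 2), and without subcutaneous T2DM library 5 their median was -0.16 (adjusted p = 0.405). Without subcutaneous DJB library 5 the call ended for adipocyte markers (-1.76, then -0.38 with adjusted p = 0.511), lipolysis (-1.46, then -0.63 with adjusted p = 0.499) and adipocyte differentiation (then -0.45 with adjusted p = 0.375). Lipolysis also lost it without visceral or subcutaneous T2DM library 5 (0.0535 and 0.0501). Without subcutaneous DJB library 2 it ended for T and NK cell (-2.93, then -0.43 with adjusted p = 0.722) and B and plasma cell markers (-3.48, then -0.87 with adjusted p = 0.558) and for glucocorticoid response (0.55, then 0.57 with adjusted p = 0.0728). Macrophage markers (0.77) lost it without visceral T2DM library 3 (0.0968) or subcutaneous T2DM library 5 (0.380, median 0.05). Mammary and skin epithelium markers (-2.42) lost it without subcutaneous T2DM library 5 (0.195), visceral DJB library 2 (0.0715) or subcutaneous DJB library 4 (0.118, median -0.85). With TPM scaling the medians were -0.76 for adipocyte differentiation, 0.92 for glucocorticoid response, 0.90 for stromal progenitors and 1.37 for macrophages. Lists that passed only without 1 library were cell cycle (subcutaneous T2DM 2 and DJB 3 and 5), immediate early genes (visceral T2DM 1 and DJB 6, subcutaneous DJB 3 and 4), fatty acid synthesis (subcutaneous T2DM 5 and DJB 4), blood markers (subcutaneous T2DM 2, visceral DJB 2), and adipokines, inflammatory cytokines and interferon response (subcutaneous DJB 2). Their camera adjusted p was 0.00364 to 0.0466.

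No single gene was called for the interaction by edgeR (0 genes, 1957 at an unadjusted p under 0.05, smallest adjusted p 0.120), and limma called 0 with either pseudocount (898 and 840) and DESeq2 123 (23 higher, 100 lower). Krt7 (-6.91) and Upk1b (-6.41) of epithelium, Cd3g of T cells (-4.92), Igfbp2 (-4.92), Pde3b of insulin signalling (-2.56) and Stat3 (1.13) had adjusted p values of 0.120 to 0.269. Adipoq had -2.56 (SE 1.04, adjusted p = 0.288 by edgeR), Ghr -0.25, Igf1 -0.58, Stat5a 1.54, Stat5b 0.81, Socs2 0.57, Cish 1.26, Jak2 0.74, Adipor1 0.03, Adipor2 -0.18, Lep -0.71, Pparg -1.52, Slc2a4 -1.76, Insr 1.11 and Ucp1 -7.23. The high Ucp1 level of visceral T2DM library 5 enters the last value. Of the 62 axis genes 0 were called, and 1 (Fndc5) passed adjusted over the list alone. A single gene was called without visceral T2DM library 5 and 1 without visceral T2DM library 6. TPM scaling moved the median of all genes from -0.07 to 0.28.

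The DJB effects in the depots were weakly related across genes, which are not independent replicates. The fitted log2 fold changes of the 14019 genes had Pearson r = 0.116 and Spearman rho = 0.114, and 55.1% of genes had the same sign. With group means of log2 CPM r was 0.201, and 26 of 100 random splits of the libraries within each depot gave an r as far from 0 (range -0.358 to 0.404). Of the 658 genes called in visceral fat, 395 (60.0%) had the same sign in subcutaneous fat, and 0 genes were called in both depots.

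Within T2DM, visceral fat differed from subcutaneous fat in developmental regulators and in the share of adipocyte and mammary genes. Tcf21 and Wt1, transcription factors of visceral mesoderm, were 168-fold (log2 7.39, SE 0.89, adjusted p = 0.000158 by edgeR) and 80.9-fold (6.34, SE 0.83) higher in visceral fat, and Tbx15, a subcutaneous patterning gene, was lower by 35.9-fold (-5.17, SE 0.61). Of 10 visceral developmental genes 6 were higher (median 1.57; Gata6 1.75, Nr2f1 1.38), and of 9 subcutaneous ones 2 were lower (median -0.28; Shox2 -1.93), with adjusted p = 0.00409 and 0.337 with an estimated correlation. Adipoq was 12.2-fold higher (log2 3.60, SE 0.82, adjusted p = 0.0103 by edgeR) and Pparg 4.46-fold higher in visceral fat, and the signal transducer genes Stat5a and Stat5b were lower by 5.91-fold (adjusted p = 0.00191 by edgeR) and 1.84-fold. Stat5a was at 246, 177, 168 and 409 CPM in subcutaneous T2DM libraries 1 to 4, the 4 with the high Csn1s1 given above. It was at 39.7 CPM in library 5, against 22.1 to 73.3 CPM in visceral T2DM. Of 17 adipocyte markers 10 were higher (median 2.85; Tmem120a 2.85), of 25 lipolysis genes 11 higher and 1 lower (median 2.31; Pde3b 2.97, Cidea 4.08, Hcar2 2.81) and of 22 adipocyte differentiation genes 8 higher (median 1.51; Adig 4.43, Cebpa 2.83). Each of these 3 lists had adjusted p = 0.305 with an estimated correlation. With TPM scaling the medians were 0.97 for visceral and -0.83 for subcutaneous developmental genes, 1.88 for adipocyte markers and 0.94 for adipocyte differentiation.

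Mitochondrial genes in T2DM were also higher in visceral than in subcutaneous fat: 67 of 73 for oxidative phosphorylation (median 2.25; Cycs 2.96, Ndufb6 2.76), 17 of 20 for the tricarboxylic acid cycle (1.63; Idh2 1.85), 11 of 24 for fatty acid oxidation with 1 lower (1.42; Cpt1b 5.06 and Etfb 2.55 higher), 5 of 17 thermogenic genes (1.54) and 5 of 21 for branched-chain breakdown (0.93; Mccc2 1.59). These 5 had adjusted p = 0.305 to 0.489 with an estimated correlation. With TPM scaling the medians were 1.06, 0.94, 0.54, 0.75 and 0.29 in the same order. Visceral T2DM libraries 2 and 5 stood highest for oxidative phosphorylation here as well. Cholesterol synthesis (5 of 24 higher, median 0.44; Acat2 2.10, Insig1 2.07, Fdft1 1.43), inflammatory cytokines (4 of 23, 0.63; Il6 4.77, Cxcl1 4.08, Cxcl2 4.06), immediate early genes (1 of 17, 0.91; Junb 2.83-fold), gut hormone receptors (1 of 8, 1.00; the secretin receptor gene Sctr 2.95), mesothelium markers (3 of 11, 0.69) and blood markers (0 of 7, 1.96) were higher as lists (adjusted p = 0.305 to 0.587 with an estimated correlation). Their medians with TPM scaling were 0.04, 0.13, 0.52, 0.20, 0.33 and 1.05 in this order. Adipokine genes (4 higher and 1 lower of 23; Rbp4 3.45, Agt 2.35, Lcn2 -4.37) had a median of 0.38, which was -0.22 with TPM scaling, and adjusted p = 0.426 with an estimated correlation. Extracellular matrix (4 of 32 lower, median -0.52; Col1a1 -3.91, Tgfb3 -2.65, Tgfb2 -2.20), circadian clock (2 of 18 lower, -0.80; Bhlhe41 -2.34, Hlf -2.32) and mammary and skin epithelium markers (6 of 15 lower, -0.94; Elf5, Csn3, Csn1s1 and Lalba between -7.77 and -7.61) were lower (adjusted p = 0.720, 0.337 and 0.426 with an estimated correlation), and matrix genes had -1.10 with TPM scaling. The clock mean log2 CPM was 4.98 to 5.73 in subcutaneous T2DM libraries 1 to 4, which had the high Csn1s1, and 4.57 in library 5. In visceral T2DM it was 3.62 to 4.70. The largest single-gene differences were in urothelial and other epithelial genes high in visceral T2DM libraries 2, 3 and 4 (Upk3a 8.93, Upk2 8.35, Uchl1 7.78, Upk1a 7.75, Sprr1a 7.67, Krt7 6.47), in the pancreatic enzyme gene Cpa1 (7.16, with 397 CPM in visceral T2DM library 2 alone), and in genes of the secretory mammary epithelium or other glands (Cyp24a1 -9.07, Slc13a2 -8.84, Btn1a1 -8.69, Aqp5 -8.56, Lrrc26 -8.49, Muc4 -8.48, Itprid1 -8.45). Ccl28 had 4 counts over the visceral and 3777 over the subcutaneous T2DM libraries.

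Camera called 20 of 38 lists between the depots in T2DM, 16 higher and 4 lower in visceral fat. With an estimated correlation only the visceral developmental genes passed (adjusted p = 0.00409), and the others had adjusted p = 0.305 to 0.720. In the exact test of list means 12 lists passed (adjusted p = 0.0206 to 0.0480), among them visceral developmental genes (difference 2.10) and adipocyte markers (2.92). List calls ended for extracellular matrix without visceral T2DM libraries 3 or 5 or subcutaneous library 5 (camera adjusted p = 0.130, 0.135 and 0.442, the last with a median of 0.07), for immediate early genes without visceral library 1 (0.139), for mesothelium without visceral library 4 or subcutaneous library 5 (0.0656 and 0.101) and for subcutaneous developmental genes without subcutaneous library 5 (0.0692). Lists that passed only without 1 library were cell cycle (visceral 2, subcutaneous 1 and 4), fatty acid synthesis (visceral 5, subcutaneous 5), insulin signalling (visceral 2), Schwann cells (subcutaneous 4 and 5), stromal progenitors (subcutaneous 4) and macrophages (subcutaneous 5), with camera adjusted p from 0.000703 to 0.0494. EdgeR called 1222 genes, 762 higher and 460 lower in visceral fat (3452 at an unadjusted p under 0.05), and of the 62 axis genes 8 (5 higher, 3 lower), or 11 adjusted over the list alone. The 8 became 4 without visceral T2DM library 5 or subcutaneous T2DM libraries 2 or 4, 5 without subcutaneous T2DM library 1, 4 without visceral T2DM libraries 2, 3 and 4 and 2 without libraries 2 and 5. They were 1 with the mitochondrial share as a covariate, 5 with TPM scaling or when only the groups compared were fitted, 5 and 4 by limma with the larger and smaller pseudocount and 14 by DESeq2. The call for Stat5b ended without visceral T2DM libraries 3 or 5 or subcutaneous T2DM libraries 1 to 4 (adjusted p = 0.0594 to 0.0940 by edgeR). Igf1 (1.57), Slc2a4 (1.77), Ucp1 (7.75, with the high level of visceral T2DM library 5 given above), Ghr (1.28), Lep (2.34), Adipor1 (0.17), Adipor2 (0.99), Jak2 (-0.46), Cish (lower by 2.00-fold), Socs2 (0.03) and Insr (-0.39) did not pass.

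The direction of the T2DM depot count depended on scaling. TPM scaling gave 485 genes, 90 higher and 395 lower, with the median of all genes at -0.46 in place of 0.02. Limma gave 712 genes (236 higher, 476 lower) and 636 (217 higher, 419 lower), DESeq2 1964 (1276 higher, 688 lower), a fit of the groups compared 577 and the mitochondrial share as a covariate 157. Without visceral T2DM libraries 2, 3 and 4 it was 797 and without libraries 2 and 5 it was 454. Leaving out a single library moved the count past 1.5 times for visceral T2DM library 2 (794), 5 (781) and subcutaneous T2DM libraries 1 (691), 2 (620), 3 (797) and 4 (575).

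After DJB the developmental genes again separated the depots. Wt1 was 134-fold (log2 7.07, SE 0.86, adjusted p = 0.000653 by edgeR) and Tcf21 92.4-fold higher in visceral fat, Osr1 had 2.52, and Tbx15 (-4.43) and Hoxd10 (-2.36) were lower. The inflammatory genes Ptx3 (6.76), Il6 (5.47), Cxcl2 (4.84) and Cxcl1 (4.59), the retinol dehydrogenase gene Rdh12 (4.01) and Tubb3 (3.53) were also higher, and Ptx3 was at 453 and 516 CPM in visceral DJB libraries 5 and 6 and at most 9.23 CPM in the other 4. In the same 2 libraries Il6 was at 295 and 167 CPM (3.38 to 51.3 in the other 4) and Cxcl1 at 443 and 132 (19.1 to 65.7). Cxcl2 was at 65.5 CPM in library 5 and 3.69 to 12.1 in the other visceral DJB libraries. Grb14 of insulin signalling (1.61) and the metallothionein gene Mt2A (3.04) were higher as well. Subcutaneous fat was higher in milk genes (Csn2 -6.98, Csn3 -6.88, Lalba -6.12 and Elf5 -5.82, as visceral minus subcutaneous), in B cell genes (Cd79a -6.37, Cd22 -3.73, Ighg1 -10.31, Igh-6 -7.98), in Tcf7 (-3.03) and Sox10 (-3.67), and in Smr3b (-7.67), Clca1 (-7.49), Crabp1 (-7.35) and Hhipl2 (-7.10). Igh-6 was at 7021 CPM in subcutaneous DJB library 2 and at 1.63 to 104 in the other subcutaneous DJB libraries. Ighg1 was at 3100 and 0.121 to 14.6 CPM, and Cd79a at 412 and 1.11 to 69.2 CPM, in the same order. Glycam1 had 12 counts over the visceral and 28401 over the subcutaneous libraries, and Scgb2a2 had 0 and 502.

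By list after DJB, visceral developmental genes (3 of 10 higher, median 0.59), inflammatory cytokines (3 of 23, 0.89), immediate early genes (0.80), endoplasmic reticulum stress (0.57; Pdia6 1.24), macrophage (0.74; Cd14 0.99), adipocyte (0.88; Lpl 0.96) and endothelial markers (0.54) and lipolysis genes (0.59) were higher in visceral fat. The same held for adipocyte differentiation (0.43), adipokines (0.36), adiponectin receptors (0.32), gut hormone receptors (0.33), glucocorticoid response (0.26), cholesterol synthesis (0.21) and insulin signalling (0.20). With an estimated correlation the first had adjusted p = 0.00302 and the others 0.278 to 0.385. Extracellular matrix genes passed with a median of 0.01, which was -0.33 with TPM scaling (adjusted p = 0.574 with an estimated correlation). Mammary and skin epithelium markers (6 of 15 lower, -4.54), B and plasma (4 of 10 lower, -4.46) and T and NK cell markers (1 of 19 lower, -3.01), cell cycle (-1.34; Mki67 -2.79, Mcm3 -2.44), Schwann cell markers (-1.07) and subcutaneous developmental genes (2 of 9 lower, -0.57) were lower, with adjusted p = 0.111 for epithelium markers and 0.288 to 0.447 for the others with an estimated correlation. Without subcutaneous DJB library 2 the medians were -1.98 for B and plasma cells, -0.22 for T and NK cells and -0.27 for cell cycle, and 0.56 for adipocyte and 0.26 for endothelial markers, 0.35 for lipolysis, 0.14 for adipocyte differentiation, 0.07 for adipokines, 0.18 for adiponectin receptors, 0.10 for gut hormone receptors and 0.17 for glucocorticoid response. With TPM scaling they were 0.38 for visceral developmental genes, 0.39 for lipolysis, 0.34 for endothelial markers, 0.17 for adipocyte differentiation, 0.20 for adipokines, 0.15 for adiponectin receptors, 0.11 for gut hormone receptors, 0.04 for glucocorticoid response, 0.07 for cholesterol synthesis and 0.09 for insulin signalling.

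Camera called these 22 of 38 lists after DJB. In the exact test of list means visceral developmental genes (difference 1.93) and mammary and skin epithelium markers (-4.27) passed (adjusted p = 0.0411). Without subcutaneous DJB library 2 the camera calls ended for adipocyte differentiation (adjusted p = 0.307), adipokines (0.307), adiponectin receptors (0.165), cell cycle (0.445), extracellular matrix (0.463, median -0.24), T and NK cells (0.980) and endothelial markers (0.116), and those for Schwann cells ended without visceral DJB libraries 5 or 6 (0.0660 and 0.0691) or subcutaneous DJB libraries 3 or 5 (0.258 and 0.134). Lists that passed only without 1 library were branched-chain breakdown (subcutaneous 4 and 5), the tricarboxylic acid cycle (visceral 3 and 6, subcutaneous 5), oxidative phosphorylation (subcutaneous 4), thermogenic genes (subcutaneous 5), fatty acid synthesis and interferon response (subcutaneous 2) and stromal progenitors (subcutaneous 1). The same held for blood (visceral 5 and 6, subcutaneous 4), intestinal epithelium (visceral 1 and 2, subcutaneous 2 and 3), skeletal muscle (visceral 3, subcutaneous 5) and smooth muscle markers (visceral 5 and 6, subcutaneous 3 and 4). Camera adjusted p for these was 0.00297 to 0.0498.

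EdgeR called 185 genes between the depots after DJB, 32 higher and 153 lower in visceral fat (2028 at an unadjusted p under 0.05). Of the 62 axis genes 1 was called, and adjusted over the list alone Ptpn6 was added. By edgeR 0 axis genes were called without any 1 visceral DJB library or without subcutaneous DJB library 2 or 4, while 7 axis genes were called without subcutaneous DJB library 5 and 2 without library 3. The count was also 0 with TPM scaling, with no filter, by limma with either pseudocount and when only the groups compared were fitted. It was 2 with the FPKM 5 filter, the length-trend correction or the mitochondrial share as a covariate, and 5 by DESeq2. Adipoq (1.04, SE 0.74, adjusted p = 0.583 by edgeR), Ghr (1.03), Igf1 (0.99), Stat5a (-1.03), Stat5b (-0.07), Socs2 (0.60), Cish (0.26), Jak2 (0.28), Adipor1 (0.20), Adipor2 (0.81), Lep (1.63), Pparg (0.63), Slc2a4 (0.01), Insr (0.72) and Ucp1 (0.51) did not pass. TPM scaling gave 165 genes, 11 higher and 154 lower, with the median of all genes at -0.16 in place of -0.04. Limma called 15 and 12 genes, DESeq2 719, a fit of the groups compared 7, the fit without a filter 110, the FPKM 5 filter 123 and the length-trend correction 303. Without single libraries the count was 6 (subcutaneous DJB 4), 114 (2), 282 (1), 383 (3) and 486 (5), and 10, 10, 11, 19, 33 and 41 without visceral DJB libraries 5, 6, 1, 4, 2 and 3. Wt1, Tcf21 and Tbx15 passed in each of these fits.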

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

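The tests of explanations, the fits without named visceral T2DM libraries, the length-trend correction and the counts over other splits in this part were chosen after the results were seen.

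The first pattern is the excess of lower genes in visceral fat after DJB, 599 of 658, with a median log2 fold change of -2.17 (-0.75 without visceral T2DM libraries 2 and 5, and -1.34 without libraries 2, 3 and 4). For fatty acid oxidation the tables argue against short transcripts enriched in T2DM libraries 2 and 5 as the whole cause, since the list median with the length trend removed was -1.74 (SD over genes 0.58), while for oxidative phosphorylation, whose transcripts are short (median length -1.63 on the log2 scale relative to all genes), it was -1.22 (SD 0.46) and length and regulation cannot be told apart, because the list and the trend overlap. Without T2DM libraries 2 and 5, which were chosen for their high values, the medians were -0.36 for oxidative phosphorylation and -0.80 (SD 0.51) for fatty acid oxidation, so high levels in those 2 libraries and regulation cannot be told apart by these fits. Library 5 also had Ucp1 at 2944 CPM, against 1.20 to 265 in the other T2DM libraries. Its mean log2 CPM of fatty acid oxidation genes was 8.90, against 5.80 to 6.97. Library 2 held the pancreatic enzyme gene Cpa1 at 397 CPM, against 2.28 to 6.92. Whether the tissue composition of these 2 samples gave the high levels was not tested. All 13 tested urothelial genes were higher in each of T2DM libraries 2, 3 and 4 than in the other 9 visceral libraries. They were chosen for those values, so urothelial tissue in the 3 samples and regulation cannot be told apart by this count. Of the 599 lower genes, 139 (23.2%) were likewise higher in each of these 3 libraries, against 2.67% of all tested genes. The lower genes were called from the same libraries, which raises their share, so it does not decide either. A lower expression of oxidation genes after DJB stays open as an untested biological explanation, because a change of tissue composition in T2DM samples could give the same values.

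Other splits of the libraries were counted for each comparison, with the real one among 100. In visceral fat 2 splits gave as many genes (real count 658, highest other 734). Between the depots in T2DM 3 did (1222, highest other 1593), and between the depots after DJB 1 did (185, highest other 1). These 3 shares lie under 0.05, without adjustment over the comparisons. Because another split called more genes than the real one in visceral fat and between the depots in T2DM, these shares do not exclude chance there. By the count at an unadjusted p under 0.05, 5 splits were as large in visceral fat (real 3106, highest other 3532). Between the depots 5 were in T2DM (real 3452, highest other 3995) and 2 after DJB (real 2028, highest other 2498). Only the last share lies under 0.05. In visceral fat the count of called genes was also 1 to 7 without DJB library 1, 2, 3, 5 or 6. In subcutaneous fat and for the interaction the real count of called genes was 0, which 100 of 100 splits reach by definition (highest other 236 and 516), so that count tests nothing. By the unadjusted count 15 splits were as large in subcutaneous fat (real 1259, highest other 2346) and 10 for the interaction (real 1957, highest other 3264), so chance cannot be excluded there. Single splits that call 236 and 516 genes point to a structure of the samples, which was not tested, and the next highest splits called 1 and 111 genes.

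Libraries were picked out where the gap between the highest or lowest library and its nearest neighbour in the group was a large share of the group's range. The share is given for each, and chance alone picks about 1 in 20 groups; here it was 25 of 154 groups for named genes, 15 of 152 for list means and 2 of 12 for library measures.

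Visceral T2DM library 2 had the lowest Adipor2 (0.638), Lep (0.745) and Insr (0.706), the lowest means for insulin signalling (0.848), glucocorticoid response (0.754) and circadian clock genes (0.742), the highest Cpa1 (0.785) and the most total counts (0.774). Visceral T2DM library 5 had the highest Stat5a (0.664), the highest means for the tricarboxylic acid cycle (0.646) and endoplasmic reticulum stress (0.714) and the lowest for visceral developmental genes (0.646). Ccl28 was highest in visceral T2DM library 4 (1).

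Visceral DJB library 2 had the lowest Upk3a (0.638), Sptssb (0.806), Clca1 (0.760) and mammary and skin epithelium mean (0.759). Bnipl was highest in visceral DJB library 5 (1), Krt20 in library 4 (1) and Glycam1 in library 1 (1), genes with few counts in that group. Branched-chain amino acid breakdown was highest in visceral DJB library 4 (0.684).

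Subcutaneous T2DM library 5 had the lowest Stat5b (0.761), Insr (0.759), Ccl28 (0.759), Slc13a2 (0.764), Btn1a1 (0.821), Aqp5 (0.856), Lrrc26 (0.816), Muc4 (0.783) and Itprid1 (0.794), and the lowest means for mesothelium (0.774) and mammary and skin epithelium (0.834). Slc2a4 was lowest in subcutaneous T2DM library 4 (0.835), Tcf21 lowest in library 1 (0.837) and B and plasma cell markers highest in library 2 (0.751).

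Subcutaneous DJB library 2 had the lowest Tcf21 (0.876), subcutaneous developmental mean (0.744) and endothelial mean (0.864), and the highest Il6 (0.746) and interferon response mean (0.838). The tricarboxylic acid cycle mean was highest in subcutaneous DJB library 5 (0.728), and the milk gene share in library 4 (0.723).

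A different DJB effect in the depots, by the interaction term and camera with the preset correlation, picked out 20 lists, given as the median visceral minus subcutaneous effect. Negative values were -2.22 for oxidative phosphorylation, -1.45 for the tricarboxylic acid cycle, -1.28 for fatty acid oxidation, -0.79 for branched-chain amino acid breakdown, -1.50 for thermogenic genes, -1.46 for lipolysis, -1.33 for adipocyte differentiation, and, for markers, -1.76 for adipocytes, -2.93 for T and NK cells, -3.48 for B and plasma cells, -3.34 for mesothelium and -2.42 for mammary and skin epithelium. Positive values were 0.31 for growth hormone signalling, 0.71 for extracellular matrix, 0.74 for endoplasmic reticulum stress, 0.55 for glucocorticoid response, 0.64 for circadian clock, and, for markers, 0.48 for stromal progenitors, 0.77 for macrophages and 0.66 for endothelium. None of the 20 passed with an estimated correlation.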

How the results depend on the processing

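Fits without several named libraries, with the mitochondrial genes left out, with a mitochondrial or milk covariate and with the length trend removed were chosen after the data were seen. Counts of genes are given as visceral, subcutaneous, interaction, depot in T2DM and depot after DJB, against 658, 0, 0, 1222 and 185. Median-ratio scaling, robust estimation, no dispersion trend, a 2-fold minimum and leaving out the mitochondrial genes moved none of these by more than 1.5 times, and none of them moved the 6 axis genes in visceral fat so far.

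TPM scaling gave 115 (visceral), 485 (depot, T2DM) and 2 axis genes. Without a filter there were 237 (visceral), 110 (depot, DJB) and 3 axis genes, and with a filter of FPKM 5 there were 123 (depot, DJB). Limma on log2(FPKM + 1) gave 0 (visceral; 1765 at an unadjusted p under 0.05), 712 and 15 for the depots and 0 axis genes, and on log2(FPKM + 0.1) 0 (visceral; 1786), 636, 12 and 0 axis genes. DESeq2 gave 1459, 168, 123, 1964 and 719, and 11 axis genes. Fitting the compared groups alone gave 1 (visceral), 577, 7 and 0 axis genes. Leaving out visceral T2DM libraries 2, 3 and 4 gave 0 (visceral, edgeR; 1436 at an unadjusted p under 0.05), 797 (depot, T2DM) and 0 axis genes, and leaving out libraries 2 and 5 gave 73, 454 and 2. The mitochondrial share as covariate gave 157 (depot, T2DM), and the length-trend correction gave 277 (visceral) and 303 (depot, DJB). An estimated correlation gave 0, 0, 0, 1 and 1 lists in place of 13, 8, 20, 20 and 22. The cause of these differences was not tested, except that leaving out libraries leaves fewer samples.

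Leaving out each library in turn gave 1 to 1744 genes in visceral fat, 0 to 29 in subcutaneous fat, 0 to 1 for the interaction, 575 to 1779 and 6 to 486 for the depots, 1 to 14 axis genes in visceral fat, and 13 to 16, 8 to 14, 15 to 21, 19 to 23 and 18 to 26 lists. The similarity of the effects in the depots lay between 0.0446 and 0.184 under the alternatives run for it.

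No pairing by replicate number was seen: correlations between libraries of the same number ran from -0.171 to 0.315, and at most 2 of 6 matched their own number best. Between the depots within a group they ran from -0.167 to 0.276 over 5 pairs each. Low correlations do not rule out that a number marks 1 rat in both depots, which the labels do not say. With the number as a block the counts were 1 (visceral), 82 and 0 for the depots, 1 axis gene in visceral fat and 0 in either depot comparison. The 1 axis gene was higher after DJB, so the call for Fndc5, which was lower, ended in that fit.

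Lep in subcutaneous fat (1.65) was -0.090 with limma on log2(FPKM + 0.1), -0.18 with the replicate block and -1.01 without subcutaneous DJB library 5, where Adipoq (1.38) was -0.31. Over all libraries left out in turn Lep ranged from -1.01 to 2.94 and Adipoq from -0.31 to 2.02. Insr between the depots in T2DM (-0.39) was 0.21 with the mitochondrial share as covariate. Values that were not called and lay within 1 SE of 0 also changed sign under some alternatives, for 5 named genes in visceral fat, 6 in subcutaneous fat, 5 for the interaction, 2 between the depots in T2DM and 4 after DJB. Of all other values for named genes, these included, 1463 kept their side of the threshold in visceral fat, 720 lost the call and 32 gained it, in subcutaneous fat 928, 0 and 25, for the interaction 1129, 0 and 8, between the depots in T2DM 1708, 192 and 18 and after DJB 971, 304 and 16. Depth limits genes with few counts, such as Bnipl and Krt20 with 7 counts in visceral DJB, whose folds are uncertain.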

Other observations

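The list of 30 genes and the tests of explanations in this part were chosen after the results were seen, so their p-values do not stand as independent evidence.

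Ido1, Igtp, Irgm and Wdr31 were lower in every DJB library than in every T2DM library within both depots, and Hnrnpm and Kpna1 were higher. If the samples of the depots are independent, 0.0602 genes in each direction would be expected by chance. Rats shared between the depots, which the labels do not exclude, could make this number too low. Because 3 of the lower genes are induced by interferon gamma, 30 such genes were examined. Their mean log2 CPM in visceral fat was 5.71 ± 0.44 (SD, n = 6) in T2DM and 4.50 ± 0.45 (n = 6) in DJB (exact p = 0.00216, the smallest this design can give), with 29 of 30 log2 fold changes negative (median -1.10, or -0.95 with TPM scaling) and 6 genes called. In subcutaneous fat it was 5.67 ± 0.63 (n = 5) and 4.87 ± 0.83 (n = 5; exact p = 0.143, and 0.0159 without subcutaneous DJB library 2), with 21 of 30 negative (median -0.34, or -0.70 with TPM scaling) and 0 genes called by edgeR. The permutation p over both depots was 0.00138. The interferon response list fixed earlier had a median of -0.12 in visceral fat and did not pass, except without the single libraries given above.

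The second pattern weighed is this group of interferon gamma inducible genes. A smaller share of T cells and macrophages in visceral fat is argued against by the median of 38 markers of T, NK and macrophage cells, 0.0192 (SD over markers 0.74). In subcutaneous fat the marker median was 0.10 (SD 1.86) and the same explanation cannot be told apart from regulation, since the T and NK markers follow DJB library 2 (median 2.95, and 0.37 without it) while macrophage markers (-0.44, and -0.54 to -0.70 where called without T2DM library 1, 2 or 4 or DJB library 1 or 3) lay as low as the interferon list (-0.34). With TPM scaling the visceral list median kept its sign (-0.95, against -1.10), and the exact p of the list mean was 0.0173, against 0.00216. Because the list was chosen after these libraries were seen, this p does not decide on library scaling. An effect of the bypass stays open as untested, and so does a difference in handling or sequencing of the T2DM and DJB samples, because the labels name no batches.

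The third pattern is the milk protein genes in visceral libraries, where Csn1s1 without TMM factors was at 181 to 518 CPM in 11 libraries and at 0.495 CPM (44 counts) in visceral DJB library 2. Regulation of these genes in visceral fat was not tested. Mammary tissue varying as between subcutaneous samples cannot be told apart from other sources, since the SD of the log2 milk gene share was 2.78 over all 12 visceral libraries, 0.461 without visceral DJB library 2 and 3.03 over the subcutaneous ones (lower 95% bound 2.08). Carry-over of reads from the subcutaneous libraries is in line with a visceral to subcutaneous ratio that varied little over 11 milk genes (SD 0.366 on the log2 scale). Carry-over at 1 rate for every library is argued against, since the log2 milk gene share of visceral DJB library 2 lay at -9.52 from the mean of the other 11 (SD 0.461). Carry-over at 1 rate for every gene cannot be told apart from a varying rate, since the median Ucp1 level outside the visceral T2DM group was 0.136 CPM where the Csn1s1 rate of 1.49% gives 1.59 (ratio 0.0852), while Upk1a in subcutaneous libraries gave a rate of 2.09%.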
